A study of Arabidopsis thaliana with 12 samples.

How the data were processed

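The series holds 12 samples of wild-type Arabidopsis thaliana (accession Col-0) seedlings. Global run-on sequencing (GRO-seq) and native elongating transcript sequencing (NET-seq, with the pull-downs total, unph, Ser2P and Ser5P) gave 10 libraries, 2 in each of 5 groups. A further 2 RNA-seq samples were not analysed here. For each of the 10 libraries, the deposited table gave a read count per position and strand of chromosomes 1 to 5, without normalisation, per the file headers. Reads had been aligned with Bowtie 1.1.2 to the TAIR10 genome, per the submitters' processing notes. The handling of reads with several matches, of duplicates, and the read end that a position marks were not given in the sources used here. Near-identical copies among the histone, ribosomal protein, LHCB1, LHCB2 and RBCS genes are therefore uncertain wherever they are named.

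No annotation of the deposited build was used. Gene names, symbols and extents came from a RefSeq table of assembly TAIR10.1, whose coordinates are not printed. That table carries no strand and no exons. To test that its extents fit the deposited positions, counts inside genes were compared under shifts of up to 1000 bp in steps of 100 bp, in blocks of 5 Mb, and in 26 of 26 blocks the unshifted table fitted best. The strand of a gene was taken from the counts: at least 20 counts over all libraries with at least 80% on 1 strand. Where GRO-seq or NET-seq alone had at least 10 counts, its majority had to lie on that strand too. This gave a strand to 21693 of 37899 nuclear genes and to 18840 of 27444 nuclear protein-coding genes. Of 21575 protein-coding genes with a call from both assays alone, 93.7% had the same strand in GRO-seq and NET-seq. Among protein-coding genes given a strand by this rule, a median of 97.8% of a gene's counts lay on the strand called. Counts in overlapping genes were added to each gene. The table's extents stood in for transcription start and poly(A) sites. At 179 snoRNA genes, 59.3% and 57.2% of the GRO-seq counts lay within 20 nt of the 5′ end and 47.9% to 61.6% of NET-seq counts within 20 nt of the 3′ end, so the deposited positions mark RNA 5′ ends in GRO-seq and RNA 3′ ends in NET-seq.

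Gene signal was the sum of sense counts over each gene. Genes passing edgeR's filterByExpr were tested with edgeR 4.0.16 (TMM scaling, quasi-likelihood F test) in R 4.3.3, with genes annotated as rRNA or tRNA left out of library sizes. Genes of other classes, misc_RNA among them, were not left out on that ground. The 8 NET-seq libraries shared 1 fit, and GRO-seq was compared with total in a fit of those 4 libraries. Adjusted p-values are Benjamini-Hochberg values over the genes tested in 1 comparison, with a threshold of 0.05. Fold changes are log2 values with their standard error (SE). TMM scaling sets the centre of the gene signal fold changes, so a gene that rose or fell did so relative to the other genes. Levels are CPM values scaled by TMM within the fit they belong to, given as means with the standard deviation (SD) of n = 2 libraries, so the same group has other levels in another fit. The figure of clock and heat shock genes scales all 10 libraries together. For end ratios, counts in a window were set against counts in the gene body (from 500 nt after the start to 200 nt before the end). The 5′ window was the first 300 nt and the 3′ window the 500 nt beyond the annotated end. These tests used 4304 protein-coding genes of at least 1000 bp with no same-strand neighbour within 500 bp upstream or 1000 bp downstream, in edgeR with terms for each library and for window by group. Aggregate ratios summed densities over 3750 of these genes, and 2541 of them served the antisense ratio (antisense counts in the 500 nt before the start over sense counts in the first 500 nt). Aggregates and the shares of RNA classes were compared among the 8 NET-seq libraries by an exact two-sided permutation test over the 105 ways of pairing them, whose smallest p is 0.00952. GRO-seq against any 1 NET-seq group, 2 libraries against 2, cannot go below 0.333 and was not tested in that way. Profiles used bins of 50 nt.

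The 10 gene lists were photosynthesis, circadian clock, heat shock, touch and wound immediate-early genes, histones, ribosomal proteins, SR splicing factors, flowering regulators, root markers and dividing-cell markers, with length classes under 1.5 kb and over 5 kb beside them. Root and dividing-cell markers stand for cell types whose share could differ between samples. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 12 lists and classes of a comparison, and again with the correlation estimated from the data. Named genes followed 1 rule: for each comparison, the 5 highest and 5 lowest log2 fold changes among protein-coding genes that passed the threshold, had a mean log CPM above the median and had libraries that did not overlap between the groups, plus up to 3 members of each list with the smallest p. Gene lists, tests, groups, windows, this rule and most alternatives were set before the data were examined. A fold against a group with no count in either library was computed against a floor of 3 counts over the group and is a lower bound. Floors, intervals and standard errors cover counting error and the spread between these libraries only, since reads without molecular identifiers are not independent molecules. Nothing states that replicates came from separate plants or cultures, so p-values measure the spread between libraries, which may be technical.

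The steps were tested on simulated counts drawn from the real means and library sizes. For gene signal, changed genes were drawn only from genes with a mean log CPM above the median. For the end ratios they were drawn only from genes with a minimum mean window count. Recovery at genes with fewer counts was therefore not tested. Fewer genes were changed than were called in the real gene signal comparisons, so the percentages of false calls do not carry over to them. In the unph comparison with 18794 genes, edgeR recovered 88 of 100 genes changed 2-fold and 100 of 100 changed 4-fold, and 10.5% of its calls were false. In the Ser2P comparison with 18909 genes these values were 74, 100 and 10.3%, and in the Ser5P comparison with 18861 genes 87, 100 and 8.33%. In the GRO-seq comparison with 19131 genes they were 99, 100 and 5.24%, and for Ser5P against Ser2P with 18968 genes 88, 100 and 11.7%. DESeq2 1.42.0 recovered 58 of 100 genes changed 2-fold in the unph comparison with 12235 genes, with 3.07% false calls. The end ratio test found few 2-fold changes: in the 5′ comparisons 14 of 100 (unph, 3821 genes), 10 (Ser2P, 3814 genes), 21 (Ser5P, 3821 genes) and 31 (GRO-seq, 3858 genes), and of 4-fold changes 61, 65, 66 and 75. In the 3′ comparisons it found 5, 12, 8 and 14 of 100 genes changed 2-fold and 36, 60, 48 and 66 of those changed 4-fold, with 3729, 3719, 3719 and 3812 genes. Limma on per-gene log2 ratios (pseudocount 1) recovered 0 of 100 changed genes at either fold in each NET-seq ratio comparison, so a count of 0 from it is no evidence of no change. In the 5′ comparison of GRO-seq it recovered 0 genes changed 2-fold and 3 changed 4-fold, and 91.9% of its calls there were false. Camera called a list of 20 genes raised 2-fold in each comparison and 0 or 1 of 100 random lists. The simulated genes were drawn independently, whereas estimated correlations in the real lists reached 0.82 (heat shock, GRO-seq over total). False calls of the preset correlation in such lists were therefore not tested. In 1000 sets of random values, 5.4% had a pairing p under 0.05. Simulated libraries vary only as the model assumes.

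Alternatives were DESeq2's size factors and Wald test, no filter on low counts, each replicate left out in turn, the replicate number as a block, each position counted once (presence counting), the gene body alone, other sets of libraries in the fit, shorter and longer windows, limma, medians over genes, aggregates without the 1% of genes with the most counts, and shares of protein-coding counts. Masking of counts within 20 nt of annotated small RNA genes and the leave-one-out of aggregates were added after the data were seen. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Exon, intron and splice site ratios and classes by exon number were planned and left out because the gene table has no exons. Shares of organelle RNA were left out because the tables read here cover chromosomes 1 to 5.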

Results

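Transcribing RNA polymerase II (Pol II) was profiled in 12-day-old Col-0 seedlings of Arabidopsis thaliana, raised at 20 °C with 16 h of light a day. GRO-seq lets engaged polymerases extend their RNA in isolated nuclei and sequences what they made. NET-seq (mNET in the labels) recovers RNA of 35 to 100 nt from Pol II immunoprecipitated after MNase digestion of nuclei. The pull-downs were total Pol II, a fraction the labels call unph, and Pol II phosphorylated on serine 2 (Ser2P) or serine 5 (Ser5P) of its C-terminal domain. Each of the 5 groups had 2 libraries, and the question throughout was how polymerase activity and each Pol II form are distributed over and along genes. Total counts were 9380029 and 10511159 for GRO-seq, 14942671 and 16842632 for total, and 9749359 and 8276987 for unph. They were 612436 and 12278176 for Ser2P, and 6088574 and 8035228 for Ser5P. Ser2P replicate 1 was therefore by far the shallowest library. Across genes, which are not independent replicates, log2 CPM of the 2 libraries of a group correlated with Pearson r of 0.984 for GRO-seq, 0.995 for total, 0.986 for unph, 0.899 for Ser2P and 0.986 for Ser5P. Every pair differed by more than sampling noise, with a chi-square per degree of freedom of 3.45 to 19.8. In unph, 9.37% and 13.7% of counts lay at the 100 highest positions, against 1.11% and 1.12% in total and 3.15% and 4.47% in Ser5P.

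Summed over 3750 isolated protein-coding genes, the first 300 nt carried the most signal relative to the gene body in unph and the least in Ser2P. The ratio of summed densities was 1.24 ± 0.210 in unph (SD, n = 2, as for all aggregates), 0.903 ± 0.0669 in total, 0.669 ± 0.0279 in Ser5P and 0.471 ± 0.0101 in Ser2P. GRO-seq gave 0.999 ± 0.0250. Genes with much signal weighed heavily in these sums. Without the 1% of genes with the most signal the ratios were 1.70 ± 0.254 in unph, 1.21 ± 0.0849 in total, 0.818 ± 0.0486 in Ser5P and 0.588 ± 0.00108 in Ser2P, and GRO-seq, at 1.05 ± 0.0301, lay below total instead of above it. It also lay below total with each position counted once (0.910 against 1.31). With medians over genes the ratios were 2.58 ± 0.260 in unph, 1.75 ± 0.0824 in total, 1.07 ± 0.491 in Ser2P, 1.01 ± 0.0441 in Ser5P and 1.03 ± 0.00181 in GRO-seq. Ser2P lay above Ser5P there only through replicate 1, the shallowest library, with 1.42 against 0.726 in replicate 2. These medians add a pseudocount of 1 to window and body counts, so where counts are few they depend on a library's depth. They therefore cannot order Ser2P and Ser5P. Beyond the annotated 3′ end, Ser2P had the highest ratio among the Pol II forms with 0.393 ± 0.0371, followed by Ser5P with 0.257 ± 0.0114, unph with 0.172 ± 1.40e-05 and total with 0.145 ± 0.00448. With each position counted once, unph (0.287) lay below total (0.296). GRO-seq reached 0.564 ± 0.0394 in the summed densities. Antisense signal upstream of genes was low everywhere. It amounted to 0.0110 ± 0.00137 of the sense signal in GRO-seq, 0.00541 ± 0.000461 in Ser2P, 0.00252 ± 0.000371 in unph, 0.00211 ± 0.000139 in Ser5P and 0.00171 ± 0.000183 in total. For all 3 ratios the exact permutation test over pairings of the 8 NET-seq libraries gave p = 0.00952, the smallest it can give, so libraries of 1 group lay closer together than other pairings did. The exact permutation p of the antisense ratio rose to 0.0571 with each position counted once and to 0.219 with medians over genes in place of sums. Neither alternative can show that the antisense difference was lost. Medians with a pseudocount of 1 follow a library's depth at genes with few antisense counts. Presence counting saturates where sense counts far exceed positions. The antisense medians were 0.40 and 0.0333 in the Ser2P libraries, replicate 1 being the higher, and no other group's libraries lay as far apart.

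**Figure D1:**
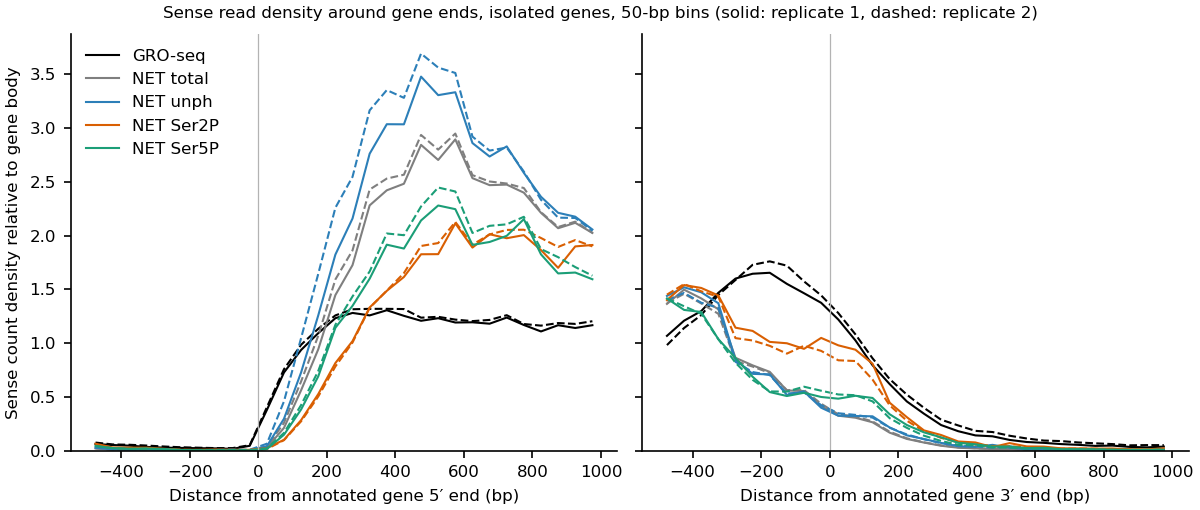
Sense count density in 50 bp bins around annotated 5′ ends (left) and 3′ ends (right) of isolated genes, relative to the gene body, with distance in bp on the x axis and 1 line per library (solid for replicate 1, dashed for replicate 2). Ser2P lies lowest after the start, with an aggregate ratio of 0.471, and highest among the Pol II forms beyond the 3′ end, with 0.393.

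**Figure D2:**
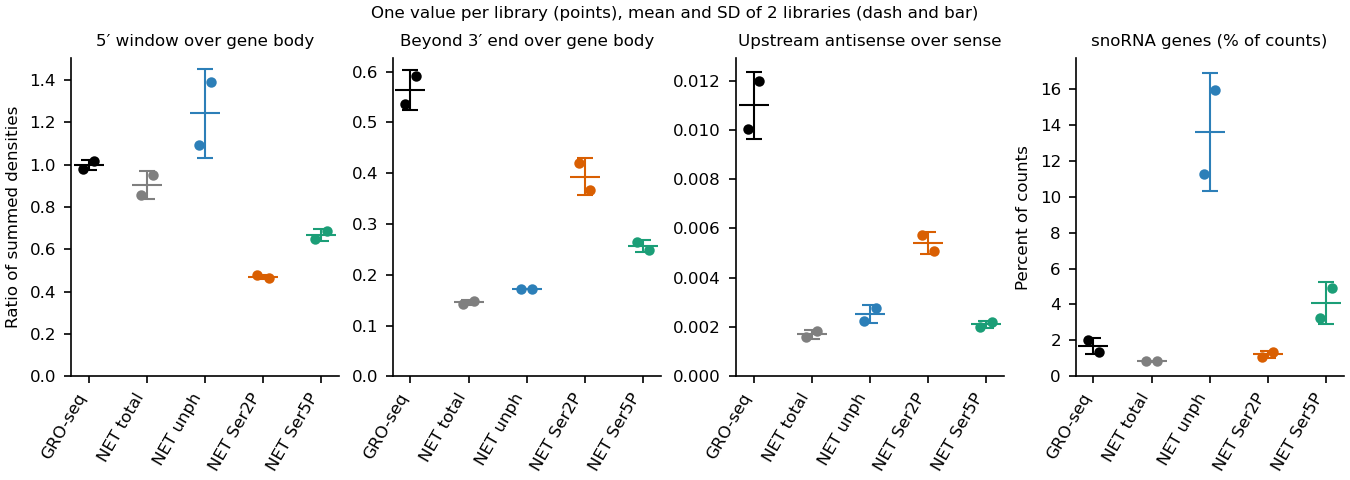
Aggregate ratio of summed densities per library for the 5′ window, the region beyond the 3′ end and upstream antisense signal, and the percentage of counts in snoRNA genes; points are libraries, dashes and bars the mean and SD of 2 libraries. The unph libraries are highest in the first panel (mean 1.24) and in the last (mean 13.6%).

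The unph pull-down was compared with total to ask where along genes this Pol II form sits. Genes with relatively more unph signal at the 5′ end included PSBQ-2 (AT4G05180), an oxygen-evolving complex subunit of photosystem II, whose 5′ ratio rose by 1.32 ± 0.27 on the log2 scale (SE; 2368 counts in the window in unph and 4594 in total). LHCA2 (AT3G61470), a light-harvesting protein of photosystem I, rose by 0.94 ± 0.26, RPL18 (AT3G05590), a ribosomal protein, by 1.17 ± 0.38, and AT5G15320 by 2.83 ± 0.60. The ratio fell at SZF1 (AT3G55980), a stress-induced zinc finger gene, with -0.86 ± 0.26 (0.54 in the first 150 nt), and at CPK32 (AT3G57530), a calcium-dependent kinase, with -1.67 ± 0.42. Of 3858 genes, 182 rose and 5 fell (edgeR with Benjamini-Hochberg adjustment), and the median over all genes was 0.52. That count stood on few libraries: it was 2 without total replicate 1, 0 without total replicate 2 and 40 without unph replicate 2, all by edgeR. Leaving out total replicate 2 still gave 405 genes at an unadjusted p under 0.05 in edgeR. Limma called 0 with 244 at an unadjusted p under 0.05. The 5′ count of edgeR was also far lower with a window of 150 nt and higher with each position counted once. Those counts are given under the dependence on processing. Beyond the 3′ end, 7 genes rose and 3 fell of 3769 (median -0.17 by edgeR, but 0.34 by limma). Among them CDF3 (AT3G47500), a photoperiod-related DOF factor, had 1.48 ± 0.36 and LBD37 (AT5G67420) 1.77 ± 0.45. A block for the replicate number gave 2 calls. Without 1 library, edgeR called 0 to 2 of these 3′ changes (0 without unph replicate 1, with 138 at an unadjusted p under 0.05; 2, 1 and 2 without total replicate 1, total replicate 2 and unph replicate 2).

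Ser2P signal was shifted from the 5′ end of genes into the region beyond their 3′ end relative to total Pol II. The 5′ ratio fell by 2.29 ± 0.30 at SZF1 (181 counts in the window in Ser2P, 1009 in total), by 3.14 ± 0.47 at SCL30A (AT3G13570), an SR-type splicing factor, and by 2.13 ± 0.32 at RBCS1B (AT5G38430), a Rubisco small subunit gene. The ratio of LHCB2.1 (AT2G05100), an antenna protein of photosystem II, fell by 1.40 ± 0.25. Beyond the 3′ end, Ser2P rose by 3.17 ± 0.35 at NPQ4 (AT1G44575), the photosystem II subunit that triggers heat dissipation, by 3.12 ± 0.34 at SVP (AT2G22540), a repressor of flowering, and by 1.54 ± 0.32 at WRKY11 (AT4G31550). At CUL4 (AT5G46210), a scaffold of ubiquitin ligases, the window beyond the end held 109 counts in Ser2P and 0 in total. The 5′ ratio of 1935 of 3858 genes fell and of 21 rose (median -1.52; -0.89 by limma, which called 400, and -2.68 without Ser2P replicate 2), and the 3′ ratio of 1259 of 3769 genes rose and of 4 fell (median 1.48), by edgeR with Benjamini-Hochberg adjustment. Counts of both directions together moved with single libraries: 1222, 918 and 343 genes at the 5′ end without total replicate 1, total replicate 2 and Ser2P replicate 2, and 520, 455 and 462 at the 3′ end. With a 5′ window of 150 nt edgeR called 671. The highest 5′ ratios, AT3G07460, AT2G27080 and AT5G11650, rested on 3 to 5 counts in Ser2P against 0 in total.

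Ser5P showed the same kind of shift, tested against total. The 5′ ratio fell by 2.19 ± 0.26 at SZF1, by 2.67 ± 0.41 at SCL30A and by 3.47 ± 0.67 at MAF1 (AT1G77080), a MADS-box regulator of flowering time. At RPL18 it fell by 1.495 ± 0.37. LHCA2 was an exception with 0.63 ± 0.26 (479 counts in the window in Ser5P and 2671 in total), although its sign turned with windows of 150 nt (-2.76) or 500 nt (-0.055). Beyond the 3′ end the ratio rose by 2.89 ± 0.31 at RBCS1B, 2.80 ± 0.33 at SVP, 2.34 ± 0.33 at NPQ4 and 1.32 ± 0.25 at DRT112 (AT1G20340), a plastocyanin gene, and UBP13 (AT3G11910), a deubiquitinase gene, fell with -3.23 ± 0.86. EdgeR with Benjamini-Hochberg adjustment called 1367 lower and 19 higher 5′ ratios of 3858 (median -1.07). It called 648 higher and 10 lower 3′ ratios of 3769 (median 0.99). A 5′ window of 150 nt and limma each called far fewer 5′ ratios, with counts given under the dependence on processing. The 5′ total of 1386 became 748 without total replicate 2, and the 3′ total of 658 became 146, 175, 236 and 341 without total replicate 1, total replicate 2, Ser5P replicate 1 and Ser5P replicate 2. Limma called 0 of the 3′ ratios, with 930 at an unadjusted p under 0.05.

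GRO-seq compares polymerases able to elongate with all immunoprecipitated Pol II. At the 5′ end, the run-on signal was relatively higher at SYP111 (AT1G08560), the cytokinesis syntaxin KNOLLE, with 3.58 ± 0.37, at SVP with 3.19 ± 0.53, at SHR (AT4G37650), a regulator of root radial patterning, with 3.14 ± 0.53, and at LHCA2 with 1.70 ± 0.19. ERF6 (AT4G17490), an ethylene response factor, had 56 window counts in GRO-seq and 0 in total. It was relatively lower at SCL30A with -4.02 ± 0.46, MAF1 with -5.03 ± 0.64 and AT5G41760 with -6.51 ± 0.47. Beyond the 3′ end nearly all changes were upward, as at LHCA2 (4.83 ± 0.37), SVP (4.18 ± 0.29), RBCS1B (3.69 ± 0.23) and DRT112 (3.53 ± 0.19), and CUL4 had 545 counts in GRO-seq and 0 in total. By edgeR with Benjamini-Hochberg adjustment, 544 of 3888 genes rose and 1658 fell at the 5′ end (median -1.10). With a window of 150 nt the balance was 476 up and 608 down of 3845 (median -0.26), and the summed ratio was higher in GRO-seq (0.724 ± 0.0259) than in total (0.301 ± 0.0334). EdgeR called 1453 of 3844 genes higher and 67 lower at the 3′ end (median 1.63). Positions mark the 5′ ends of RNA in GRO-seq and the 3′ ends in NET-seq, so the windows of the 2 assays are offset by the length of an RNA. Without total replicate 2 the 5′ total of 2202 became 1374.

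Over whole genes, edgeR called fewer genes against total in unph (1004) than in Ser2P (5847) or Ser5P (9483). Some immediate-early genes of touch and wounding rose in unph. AT5G51190, an ethylene response factor gene, rose by 1.49 ± 0.23 (148 ± 2.36 CPM against 52.7 ± 4.88, SD). RHL41 (AT5G59820), a zinc finger regulator of light and stress responses, rose by 1.31 ± 0.22. STZ (AT1G27730), a salt tolerance zinc finger gene, rose by 1.13 ± 0.24. The clock genes PRR5 (AT5G24470), PRR7 (AT5G02810) and GI (AT1G22770) fell, by 1.36 ± 0.22, 0.90 ± 0.18 and 0.82 ± 0.19. Nothing states that the unph and total plants shared a harvest time, so time of day and Pol II form cannot be told apart in clock genes. Of 23 tested touch and wound genes, 8 rose and 0 fell (10 and 0 adjusted over the list alone; 13 and 1 at an unadjusted p under 0.05; 8 and 0 by DESeq2). The list stood apart by camera with Benjamini-Hochberg adjusted p = 8.28e-05, and adjusted p = 0.720 with an estimated correlation. Of 13 clock genes, 3 fell and 0 rose (7 and 1 adjusted over the list alone; 8 and 1 at an unadjusted p under 0.05; 3 and 0 by DESeq2), with camera's Benjamini-Hochberg adjusted p = 0.00218, and adjusted p = 0.573 with an estimated correlation.

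The other lists had fewer members called in unph. Heat shock genes had a median of 0.52, close to the 0.51 of touch and wound genes. Of 11 heat shock genes, ATHSP22.0 (AT4G10250; 2.37 ± 0.54) and HSP90.1 (AT5G52640; 1.33 ± 0.37) rose, the first with 86.7% of its unph counts at 1 position. Of 16 flowering regulators, MAF5 (AT5G65080) rose by 2.47 ± 0.43, with 88.7% of its unph counts at 1 position and -0.14 when each position was counted once, and AGL20 (AT2G45660, also SOC1), a promoter of flowering, fell by 0.72 ± 0.17. No member of the lists of 52 photosynthesis genes, 34 histones, 21 ribosomal proteins, 20 SR factors, 8 root markers and 4 dividing-cell markers passed edgeR's threshold over all genes. DESeq2 called 0 in these lists too, 10 of their members had an unadjusted p under 0.05, and adjusted over the list alone 1 root marker passed. Their medians were -0.08, 0.09, 0.03, -0.16, -0.08 and -0.12, and camera called none of these lists, heat shock (adjusted p = 0.178, Benjamini-Hochberg) or the flowering list. In 2 lists and a length class the signs differed: ribosomal proteins had a mean of 0.02 but a downward test, root markers a mean of 0.12 beside a median of -0.08, and genes over 5 kb a mean of 0.0063 beside a median of -0.04. Among genes under 1.5 kb, 138 rose and 14 fell of 3395 (131 and 13 adjusted over the list alone), and over 5 kb 30 rose and 29 fell of 1348 (29 and 28 adjusted over the list alone).

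In all, 765 genes rose and 239 fell of 19199 in unph (edgeR with Benjamini-Hochberg adjustment). The largest increases were at AT4G10800 (5.27 ± 0.28; 1900 ± 273 CPM against 49.1 ± 4.66), VATG3 (AT4G25950; 5.26 ± 0.86), AT5G05735 (4.96 ± 0.59), AT1G29418 (4.95 ± 0.31) and AT3G15920 (4.75 ± 0.29). At AT4G10800, VATG3 and AT5G05735, 91.7%, 97.8% and 98.9% of the unph counts lay at 1 position, and AT4G10800 was at -1.10 over its gene body alone. With counts near annotated small RNA genes masked, AT1G29418 was at -0.34 and AT3G15920 at -0.00069. The lowest were AT4G01700 (-2.12 ± 0.44), AT4G33980 (-2.07 ± 0.22; 6.44 against 27.1 ± 2.12 CPM), FIS2 (AT2G35670; -2.004 ± 0.41), AT2G41670 (-1.84 ± 0.49) and NF-YA2 (AT3G05690; -1.78 ± 0.38). The total of 1004 genes became 449, 497 and 621 without total replicate 1, total replicate 2 and unph replicate 2. With only the 4 compared libraries in the fit it became 1621, 63.9% of them higher, against 76.2% here. Each position counted once gave 59.7% higher, and leaving out 1 library gave 71.8% to 91.5% higher.

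Heat shock genes were the group highest in Ser2P over total Pol II. HSP90.1, an inducible chaperone, reached 113 ± 27.2 CPM in Ser2P against 2.83 ± 0.585 in total (SD, n = 2), a log2 fold change of 5.36 ± 0.31 (edgeR, Benjamini-Hochberg adjusted p = 4.72e-09). HSP101 (AT1G74310), which dissolves protein aggregates, rose by 4.50 ± 0.36, the heat shock factor HSFA2 (AT2G26150) by 4.47 ± 0.46, and the small heat shock protein gene HSP17.6A (AT5G12030) by 6.08 ± 0.43. Fes1A (AT3G09350), an HSP70 co-chaperone outside the list, rose by 3.71 ± 0.25. Of 11 heat shock genes tested, 9 rose and 0 fell (9 and 0 adjusted over the list alone), with a median of 4.47 (camera, Benjamini-Hochberg adjusted p = 8.38e-20, and adjusted p = 0.0692 with an estimated correlation). DREB2A (AT5G05410), a regulator of drought and heat responses, was at 0.02 ± 0.20.

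Histone and photosynthesis genes were lower in Ser2P. Of 34 histones, 29 fell, such as HTA13 (AT3G20670; -1.68 ± 0.22) and AT5G65360 (-1.35 ± 0.20), and 0 rose (1 up and 29 down adjusted over the list alone; 1 up at an unadjusted p under 0.05 and 0 up by DESeq2), with camera's Benjamini-Hochberg adjusted p = 3.74e-17, and adjusted p = 0.294 with an estimated correlation. Of 52 photosynthesis genes, 41 fell and 0 rose (45 and 0 adjusted over the list alone; 0 up at an unadjusted p under 0.05 and by DESeq2), for example PSBX (AT2G06520; -1.28 ± 0.21) and LHCB4.2 (AT3G08940; -1.33 ± 0.24), with camera's Benjamini-Hochberg adjusted p = 7.67e-16, and adjusted p = 0.294 with an estimated correlation. Of these 41 calls, 12 were kept without total replicate 1. Of 23 touch and wound genes, 9 fell and 0 rose (the same adjusted over the list alone, unadjusted and by DESeq2), including ERF4 (AT3G15210; -1.03 ± 0.22) and DREB1A (AT4G25480; -1.02 ± 0.21), with camera's Benjamini-Hochberg adjusted p = 0.00195, and adjusted p = 0.488 with an estimated correlation. Of these 9 calls, 1 was kept without total replicate 1.

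Other lists had at most 6 members called in Ser2P. Of 16 flowering regulators, 6 rose, among them MAF3 (AT5G65060; 1.48 ± 0.21) and LD (AT4G02560; 1.33 ± 0.23), and 0 fell (camera, Benjamini-Hochberg adjusted p = 0.00998, and adjusted p = 0.449 with an estimated correlation). Of 20 SR factors, 3 rose, such as RS41 (AT5G52040; 0.95 ± 0.18), and 0 fell (adjusted p = 0.0273 by camera with Benjamini-Hochberg adjustment, and adjusted p = 0.488 with an estimated correlation). GI (0.91 ± 0.19), TOC1 (AT5G61380; 0.86 ± 0.19) and 2 further clock genes rose and 0 fell of 13, where DESeq2 called 2 and 0 were kept without total replicate 2; camera did not call the list (Benjamini-Hochberg adjusted p = 0.511). These 3 counts were the same adjusted over the list alone, and no member fell at an unadjusted p under 0.05 or by DESeq2. For the clock genes, time of day and Pol II form cannot be told apart here either. Of 21 ribosomal proteins 2 rose (RPL5B, AT5G39740, by 0.80 ± 0.20), of 8 root markers 2 fell (PYK10, AT3G09260, a root beta-glucosidase gene, by 0.59 ± 0.21), and of 4 dividing-cell markers 2 fell (SYP111 by 0.87 ± 0.21). Adjusted over the list alone these counts were 2, 2 and 3, and the dividing-cell list had camera's Benjamini-Hochberg adjusted p = 0.0327, and adjusted p = 0.449 with an estimated correlation.

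Length went with the Ser2P signal. Of 1348 genes over 5 kb, 578 rose and 25 fell (650 and 35 adjusted over the list alone; median 0.60; camera, Benjamini-Hochberg adjusted p = 9.15e-13, and adjusted p = 0.294 with an estimated correlation). Of 3395 genes under 1.5 kb, 513 rose and 1117 fell (542 and 1245 adjusted over the list alone), with camera's Benjamini-Hochberg adjusted p = 3.05e-06, and adjusted p = 0.0692 with an estimated correlation; their median was -0.47 and their mean 0.0043, opposite in sign. Over all 19199 genes, 3232 rose and 2615 fell by edgeR with Benjamini-Hochberg adjustment. The lowest were AT4G23420 (-3.63 ± 0.24, but 0.21 over its gene body alone), AT3G05675 (-3.61 ± 0.27) and AT4G05631 (-3.55 ± 0.29), and the highest besides heat shock genes was AT5G05735 (5.69 ± 0.62, with 97.9% of its Ser2P counts at 1 position). The total of 5847 became 2288, 3568 and 3400 without total replicate 1, total replicate 2 and Ser2P replicate 2, and 3434 by DESeq2. Without total replicate 2, 37.4% of the calls were higher, against 55.3% here.

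In Ser5P over total, most touch and wound genes tested rose, most photosynthesis genes fell, and clock genes went both ways. Nothing states that the plants of these pull-downs shared a harvest time. Time of day and Pol II form therefore cannot be told apart in these differences. ELF4 (AT2G40080), an evening component of the clock, reached 205 ± 37.1 CPM against 9.23 ± 2.24 in total (SD, n = 2), with a log2 fold change of 4.47 ± 0.24 (edgeR, Benjamini-Hochberg adjusted p = 1.83e-10). The evening gene TOC1 rose by 2.35 ± 0.18, and COR27 (AT5G42900), a cold-regulated gene tied to the clock, by 5.24 ± 0.22. PRR9 (AT2G46790), expressed in the morning, fell by 5.38 ± 0.25, from 153 ± 9.89 CPM in total to 3.62 ± 0.849. WRKY33 (AT2G38470), a defence regulator, rose by 3.82 ± 0.28 and TCH3 (AT2G41100), a touch-induced calmodulin-like gene, by 3.46 ± 0.25.

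Of 23 touch and wound genes, 19 rose and 2 fell in Ser5P (the same adjusted over the list alone; median 1.84; camera, Benjamini-Hochberg adjusted p = 2.15e-14, and adjusted p = 0.253 with an estimated correlation). Of 13 clock genes, 5 rose and 6 fell (5 and 8 adjusted over the list alone), and camera gave no call (Benjamini-Hochberg adjusted p = 0.643). Of 52 photosynthesis genes, 46 fell and 2 rose (46 and 3 adjusted over the list alone), such as CAB3 (AT1G29910; -3.71 ± 0.25), with camera's Benjamini-Hochberg adjusted p = 2.50e-33, and adjusted p = 0.189 with an estimated correlation. Of 34 histones, 32 fell and 0 rose (33 and 0 adjusted over the list alone; 0 rose at an unadjusted p under 0.05 and by DESeq2), AT3G46320 by 1.49 ± 0.18 (camera, Benjamini-Hochberg adjusted p = 3.96e-09, and adjusted p = 0.333 with an estimated correlation). Of 20 SR factors, 14 rose and 0 fell (15 and 0 adjusted over the list alone). DESeq2 called only 7 higher, and 0 fell unadjusted and by DESeq2. Those that rose by edgeR included SR34b (AT4G02430, 2.09 ± 0.26) and SR30 (AT1G09140, 1.56 ± 0.19). The SR list had camera's Benjamini-Hochberg adjusted p = 0.00109, and adjusted p = 0.299 with an estimated correlation.

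In the remaining Ser5P lists, 10 ribosomal protein genes fell and 1 rose of 21 (the same adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 0.0367, and adjusted p = 0.352 with an estimated correlation). Heat shock genes did not pass as a list (camera, Benjamini-Hochberg adjusted p = 0.0574), with 6 up and 1 down of 11 (8 and 1 adjusted over the list alone), DREB2A by 1.73 ± 0.19, and 2 of these calls kept without Ser5P replicate 2. Of 16 flowering regulators, 7 rose and 2 fell, AGL20 by 2.18 ± 0.19, and of 8 root markers 4 fell, SHR by 1.19 ± 0.18. Of 4 dividing-cell markers 2 fell, CYCB1;4 (AT2G26760), a mitotic cyclin gene, by 1.08 ± 0.21. Adjusted over the list alone these counts were 7 and 2, 4, and 3. Genes over 5 kb were the one group whose call held both ways: 926 rose and 56 fell of 1348 (964 and 59 adjusted over the list alone; median 0.95; camera, Benjamini-Hochberg adjusted p = 8.22e-23, and adjusted p = 0.0168 with an estimated correlation). Of 3395 genes under 1.5 kb, 659 rose and 1389 fell (678 and 1426 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 4.02e-05, and adjusted p = 0.189 with an estimated correlation). Over all 19199 genes, edgeR with Benjamini-Hochberg adjustment called 4961 higher and 4522 lower, and the total of 9483 became 6269 by DESeq2 and 6291 without total replicate 1. AT2G07240 and AT4G08878 had 0 counts in Ser5P and were at least 75.3-fold and 34.4-fold lower than in total, against a floor of 3 counts over the group. Of their counts in total, 99.5% and 97.8% lay at 1 position, so these folds stand for single positions.

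Ser5P and Ser2P were also compared directly, to ask which genes had more signal in either pull-down. Harvest time and Pol II form cannot be told apart in this comparison either. ELF4 had 205 ± 37.1 CPM in Ser5P and 6.75 ± 4.04 in Ser2P (SD, n = 2), a log2 fold change of 4.53 ± 0.27 (edgeR, Benjamini-Hochberg adjusted p = 2.75e-09). SOBIR1 (AT2G31880), a receptor kinase of immunity, rose by 3.80 ± 0.26, ERF6 by 3.79 ± 0.27 and WRKY33 by 3.66 ± 0.29, while PRR9 fell by 5.14 ± 0.25 and the morning gene CCA1 (AT2G46830) by 3.12 ± 0.24. HSP90.1 fell by 3.77 ± 0.29 and LHCA1 (AT3G54890), a light-harvesting protein of photosystem I, by 2.84 ± 0.25.

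Of 23 touch and wound genes, 21 were higher in Ser5P than in Ser2P and 0 lower (the same adjusted over the list alone, unadjusted and by DESeq2; median 2.59; camera, Benjamini-Hochberg adjusted p = 7.72e-36, and adjusted p = 0.144 with an estimated correlation). Of 11 heat shock genes, 10 were lower and 1, DREB2A, higher (the same adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 2.00e-08, and adjusted p = 0.144 with an estimated correlation). Of 52 photosynthesis genes, 39 were lower and 4 higher (the same adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 2.82e-20, and adjusted p = 0.306 with an estimated correlation). The 21 ribosomal proteins had 5 lower and 0 higher (the same adjusted over the list alone; 0 higher unadjusted and by DESeq2; camera, Benjamini-Hochberg adjusted p = 0.0227, and adjusted p = 0.507 with an estimated correlation). The 1348 genes over 5 kb had 331 higher and 78 lower (334 and 78 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 7.97e-06, and adjusted p = 0.144 with an estimated correlation). Clock genes split into 4 higher and 7 lower of 13, and the list was not called by camera (Benjamini-Hochberg adjusted p = 0.228). Camera also made no call for 34 histones (3 higher, 2 lower), 20 SR factors (4 and 1), 16 flowering regulators (1 and 4), 8 root markers (0 and 2), 4 dividing-cell markers (0 and 0; 1 and 1 unadjusted, 0 by DESeq2) and 3395 genes under 1.5 kb (482 and 681). Adjusted over the list alone these were 3 and 2, 3 and 1, 1 and 4, 0 and 2, 0 and 0, and 494 and 718. In all, edgeR with Benjamini-Hochberg adjustment called 2586 higher and 3063 lower of 19199 (median -0.14), and the total of 5649 became 3580 by DESeq2, 3681 without Ser5P replicate 1 and 3691 with only the 4 compared libraries. Of these calls 45.8% were higher, against 59.7% with 4 libraries and 58.3% with each position counted once.

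**Figure D3:**
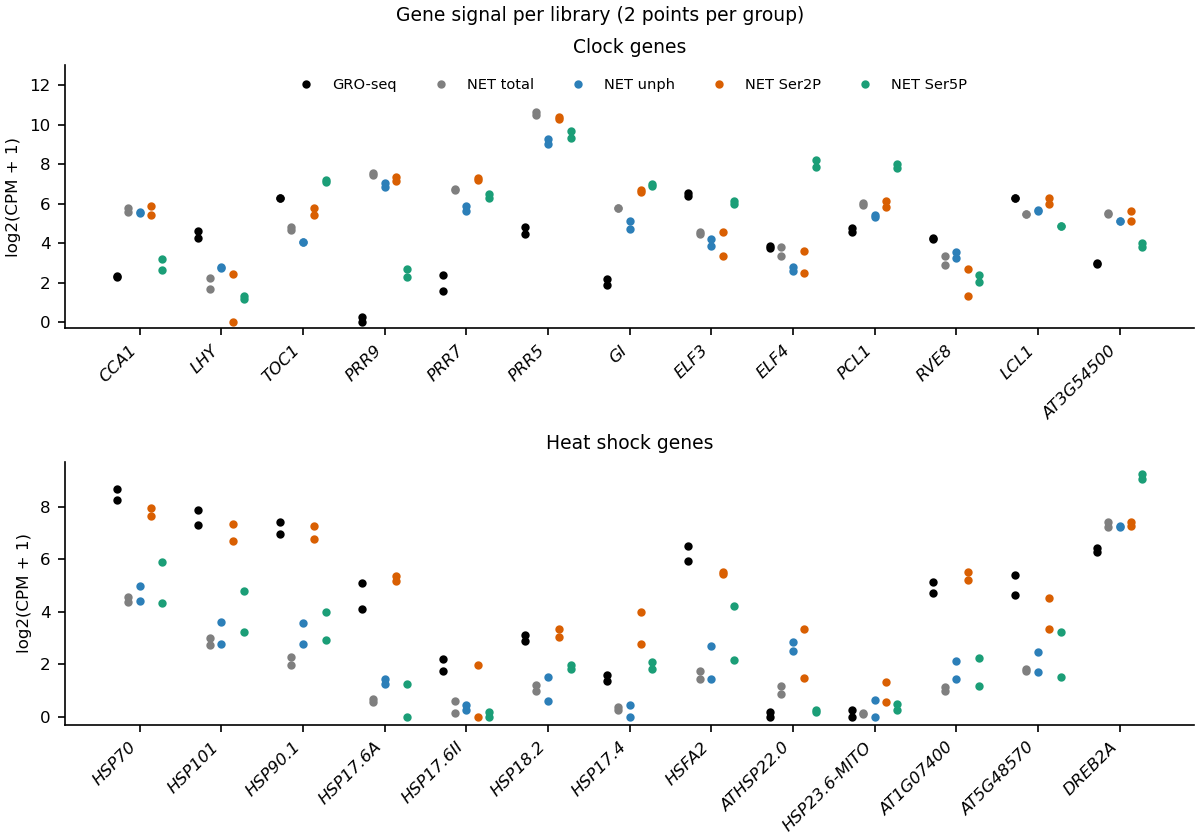
Gene signal of clock genes (top) and heat shock genes (bottom) on the y axis as log2(CPM + 1), with 1 point per library and 2 per group. PRR9 averages 182.5 CPM in total, 149.1 in Ser2P, 4.62 in Ser5P and 0.09 in GRO-seq, and HSP90.1 averages 147.3 CPM in GRO-seq and 131.5 in Ser2P against 3.37 in total.

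GRO-seq and total Pol II were compared over whole genes to set run-on activity beside Pol II occupancy. Light-harvesting genes were far lower in GRO-seq: LHCB2.2 (AT2G05070) had 1.87 ± 0.0772 CPM against 6305 ± 771 (SD, n = 2), a log2 fold change of -11.71 ± 0.30 (edgeR, Benjamini-Hochberg adjusted p = 3.43e-12), and CAB2 (AT1G29920) fell by 9.78 ± 0.27. PRR9 had 3 counts in GRO-seq (0.109 ± 0.154 CPM) and 4395 in total (241 ± 12.9 CPM), CBF2 (AT4G25470), a cold response factor, fell by 8.70 ± 0.24, and GI fell by 4.23 ± 0.16. Heat shock genes were higher, HSP90.1 by 5.30 ± 0.22, HSFA2 by 5.08 ± 0.24 and HSP101 by 4.82 ± 0.22.

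Each of the 12 lists and length classes was called by camera in GRO-seq over total, and 0 of the calls held with an estimated correlation (2 at an unadjusted p under 0.05). Of 52 photosynthesis genes 49 fell and 1 rose (camera, Benjamini-Hochberg adjusted p = 5.33e-34, and adjusted p = 0.228 with an estimated correlation). Of 34 histones 33 fell and 1 rose (camera, Benjamini-Hochberg adjusted p = 5.16e-22, and adjusted p = 0.217 with an estimated correlation). Of 23 touch and wound genes 23 fell (camera, Benjamini-Hochberg adjusted p = 1.80e-11, and adjusted p = 0.236 with an estimated correlation). All 4 dividing-cell markers fell, SYP111 by 4.19 ± 0.16. Of 9 root markers 1 rose and 6 fell, SHR with -4.42 ± 0.15 (for both lists, camera, Benjamini-Hochberg adjusted p = 0.00427 and 0.0334, and adjusted p = 0.236 for both with an estimated correlation). Of 11 heat shock genes 10 rose and 1 fell, and of 20 SR factors 17 rose and 1 fell, among them SR45a (AT1G07350; 3.01 ± 0.16). Of 16 flowering regulators 11 rose and 2 fell, MAF1 by 2.23 ± 0.14 (for these 3 lists, camera, Benjamini-Hochberg adjusted p = 2.19e-06, 0.00129 and 0.0207, and adjusted p = 0.236, 0.217 and 0.236 with an estimated correlation). Of 21 ribosomal proteins 14 rose and 3 fell, and of 13 clock genes 5 rose and 7 fell (camera, Benjamini-Hochberg adjusted p = 0.0207 and 0.00490, and adjusted p = 0.236 for both with an estimated correlation). Adjusted over the list alone, 15 ribosomal protein genes rose and 3 fell, and the other 9 lists kept the same counts.

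Among long genes, 1089 of 1348 over 5 kb rose and 126 fell in GRO-seq (1092 and 126 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 1.81e-21, and adjusted p = 0.0852 with an estimated correlation). Of 3497 under 1.5 kb, 737 rose and 2106 fell (744 and 2111 adjusted over the list alone; camera, Benjamini-Hochberg adjusted p = 3.49e-11, and adjusted p = 0.175 with an estimated correlation). Over all 19585 genes, 7671 rose and 7207 fell by edgeR with Benjamini-Hochberg adjustment, with a median of 0.12. The near balance of rises and falls follows from the TMM scaling and says nothing about total activity. AT2G07798 had 43.5 ± 8.50 CPM in GRO-seq and 0 counts in total and was at least 260-fold higher. It lies in the part of chromosome 2 that repeats the mitochondrial genome, so RNA of mitochondria can reach its count. AT4G18650 had 0 counts in GRO-seq and was at least 749-fold lower; both folds are against a floor of 3 counts over the group. CIPK20 (AT5G45820), a protein kinase gene, fell by 10.39 ± 0.28. The assays differ in chemistry and in the RNA end they mark, and plants of the 2 assays are not stated to come from 1 harvest.

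**Figure D4:**
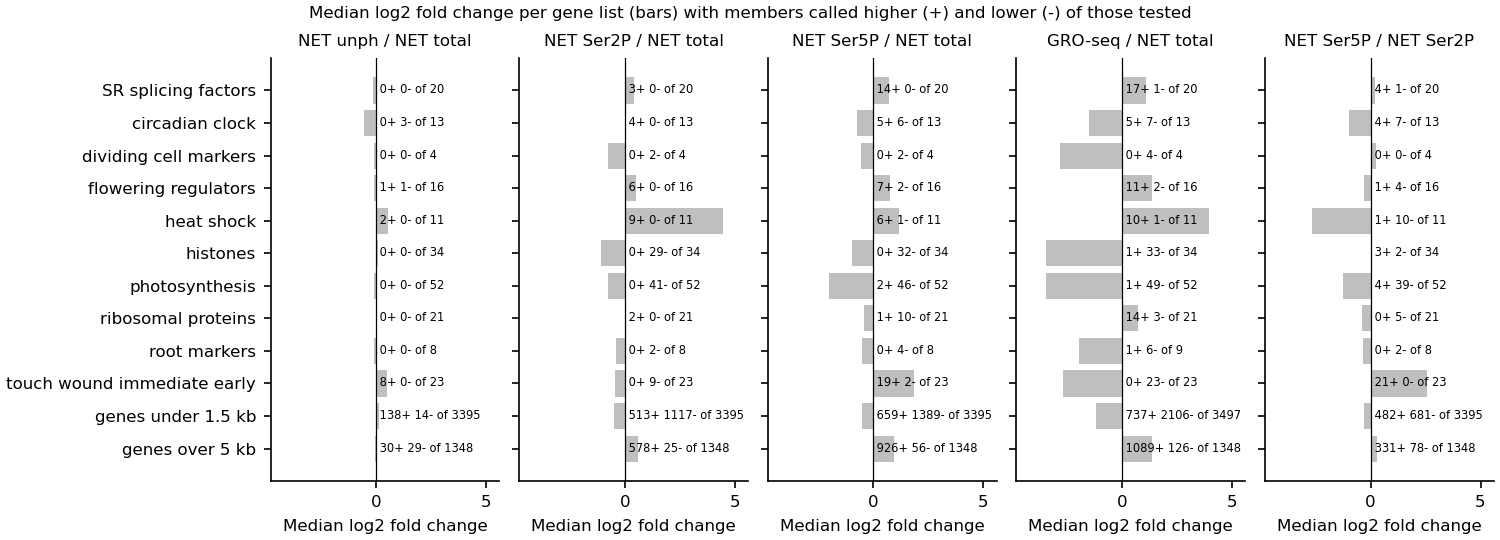
Median log2 fold change of each gene list and length class (bars, x axis) in the 5 comparisons, with the numbers of tested members called higher (+) and lower (-). Heat shock genes have a median of 4.47 in Ser2P over total and 3.95 in GRO-seq over total, and touch and wound genes 2.59 in Ser5P over Ser2P.

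Small RNA genes took unequal shares of the counts. Genes of small nucleolar RNAs (snoRNAs), which guide rRNA modification, held 13.6% ± 3.30 of counts in unph (SD, n = 2), 4.08% ± 1.15 in Ser5P, 1.69% ± 0.464 in GRO-seq, 1.22% ± 0.191 in Ser2P and 0.834% ± 0.0123 in total. Spliceosomal snRNA genes held 0.214% in GRO-seq, 0.0258% in unph, 0.0170% in total, 0.0132% in Ser5P and 0.00547% in Ser2P. Genes of tRNAs, made by another polymerase, held 0.0108% in Ser2P, 0.00813% in GRO-seq, 0.00356% in Ser5P, 0.00343% in total and 0.00135% in unph. The exact permutation test over pairings of the NET-seq libraries gave p = 0.00952 for snoRNA, the smallest it can give, and p = 0.0286 for tRNA. The highest position in unph lay on the minus strand of chromosome 5 at 26349733 (TAIR10), 3 nt beyond the snoRNA gene AT5G09515, with a mean of 5055 CPM.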

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

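The patterns below were picked from the results above; the tests of 1 aberrant Ser2P library and of handling stress were also chosen only after the values they use had been seen, while the bounds of the other tests were written before their values. A position outside the genes that the counts placed on its strand stood out. Position 8963228 on the minus strand of chromosome 3 (TAIR10) averaged 220.2 CPM in Ser2P, with 147 and 2461 counts. It had 51.6 and 106.6 CPM in unph, 5.09 and 2.85 CPM in total, 0.657 and 9.96 CPM in Ser5P, and 0 in both GRO-seq libraries, which allows up to 0.320 and 0.285 CPM. It stood out as a high signal that the gene counts leave out, because no gene called on its strand covers it. Genes without a strand call, or called on the other strand, were not searched, so it may lie inside an annotated gene.

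Of 13 clock genes, 4 were higher and 7 lower in Ser5P than in Ser2P, although camera did not call the list, with PRR9 and CCA1 lower and ELF4 and TOC1 higher in Ser5P. A few amplified positions are argued against, since 10 of the 11 clock genes called kept call and direction when each position was counted once. A harvest at another time of day may account for the pattern: in 12 other clock-controlled genes the median of 5 afternoon or evening genes exceeded that of 7 dawn or morning genes by 4.12 on the log2 scale (exact one-sided permutation test over 792 splits of genes, which are not independent replicates, p = 0.0126), where a difference above 1 had been set as needed. A direct effect of phosphorylation stays open, because nothing states that the plants were the same for each antibody: the same difference in GRO-seq over total was -0.32, within the bound of 0.5 from 0 that had been set for it, but both sets fell there (medians -2.75 and -3.07), so that comparison could not decide, a reading adopted after the value was seen. Neither explanation could be excluded, and harvest times were not given in the sources used here. In Ser5P over total the evening minus morning difference was 3.55 (exact one-sided permutation test over splits of genes, p = 0.0126). The Ser5P over total results therefore carry the same limit.

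Heat shock genes were higher in Ser2P than in total, and in GRO-seq as well. Their median over total was also 1.17 in Ser5P (6 up, 1 down of 11) and 0.52 in unph (2 up, 0 down). Total is the shared denominator of these values. Ser5P lay below Ser2P, with a median of -2.66 (10 lower, 1 higher). A single aberrant Ser2P library is argued against, since at least 8 of the 9 genes called stayed called whichever Ser2P library was left out, and so is a general stress of handling, since the 23 touch and wound genes had a median of -0.43 in Ser2P. That median lay near the -0.47 of genes under 1.5 kb, so it shows no rise of touch and wound genes, but no fall beyond that of short genes. It speaks only against a handling stress that differed between the Ser2P and the total libraries. Seedlings or nuclei that had been warm remain a candidate explanation that these values could not settle: 45.5% of 11 tested genes of a second heat-induced list rose, between the 75% and 25% set as bounds. A link between serine 2 phosphorylation and heat shock genes was not separated from this, because nothing states that the plants were the same for each antibody.

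snoRNA genes took 13.6% of counts in unph and 0.834% in total. A few genes taking most of the counts are argued against, since in a narrower set, 179 snoRNA genes with a strand counted with 20 nt on either side, the share without the 10 genes with the most counts still rose by 3.95 ± 0.36 on the log2 scale. Mature snoRNA carried through the purification may contribute: counts within 20 nt of the 3′ ends of these 179 genes rose by 4.10 ± 0.37, which was 1.05 ± 0.19 more than counts 21 to 300 nt beyond them, above the bound of 1 set beforehand by less than its SD. More Pol II on snoRNA genes stays open, since counts beyond the ends rose by 3.05 ± 0.21, although that was not within the 0.5 of the rise at the ends set as needed. Counts within 20 nt of annotated small RNA genes were left out there. Mature snoRNA from unannotated genes, or reaching past an annotated end, was not excluded. The values do not say how much each adds.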

How the results depend on the processing

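Masking small RNA genes, the leave-one-out of aggregates and the leave-one-out of shares were chosen after seeing the data; the other alternatives were planned. Among alternative values for counts of genes or lists, 119 lay within 1.5 times of the reported count and 54 did not. Among alternative exact permutation p-values of the reported results, 46 stayed under 0.05 and 2 did not. Among alternative values for named genes, 4175 kept direction and side of the threshold, 443 kept direction but lost the threshold, 45 gained it and 47 turned. DESeq2's size factors (gene signal only), no filter on low counts and masking left the counts of genes they were run on within 1.5 times. The cause was not tested for any change below, except that fewer libraries leave fewer degrees of freedom. In leave-one-out fits that leave 1 library in a group, that library is assumed to vary like the others.

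DESeq2's Wald test called 657 genes for unph, 3434 for Ser2P, 6269 for Ser5P and 3580 for Ser5P against Ser2P, and fits of the 4 compared libraries 1621 for unph and 3691 for Ser5P against Ser2P. At the 5′ end the counts were 4 (unph), 671 (Ser2P), 535 (Ser5P) and 1084 (GRO-seq) with a window of 150 nt, and 352 for unph with 500 nt. Limma called 0 (unph; 244 at an unadjusted p under 0.05), 400 (Ser2P) and 465 (Ser5P), and presence counting 594 for unph. At the 3′ end of unph the count was 2 with presence counting, 6 with 300 nt and 0 with limma (293 at an unadjusted p under 0.05), and limma also called 0 for Ser5P (930 at an unadjusted p under 0.05). With an estimated correlation camera called 0 lists in unph, Ser2P, GRO-seq and Ser5P against Ser2P (1, 2, 2 and 3 at an unadjusted p under 0.05) and 1 in Ser5P. The exact permutation p of the antisense ratio became 0.0571 with presence counting and 0.219 with medians over genes. For the 5′ ratio, medians over genes gave an exact permutation p of 0.0476, with Ser2P above Ser5P only through Ser2P replicate 1 (1.42, against 0.726 in replicate 2). Medians over genes add a pseudocount of 1, so they depend on depth where counts are few.

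Leaving out 1 library at a time gave 449 to 710 genes for unph, 2288 to 6472 for Ser2P, 6291 to 7227 for Ser5P, 12750 to 15433 for GRO-seq and 3681 to 6591 for Ser5P against Ser2P. The 5′ counts ranged from 0 to 210 (unph; 405 at an unadjusted p under 0.05 for the 0), 343 to 2097 (Ser2P), 748 to 999 (Ser5P) and 1374 to 2282 (GRO-seq). The 3′ counts ranged from 0 to 2 (unph; 138 at an unadjusted p under 0.05 for the 0), 455 to 1571 (Ser2P), 146 to 341 (Ser5P) and 1133 to 1602 (GRO-seq). Lists called ranged from 2 to 4 (unph; 4 without unph replicate 1), 5 to 9 (Ser2P; 5 without Ser2P replicate 2), 6 to 8 (Ser5P), 12 to 12 (GRO-seq) and 4 to 5 (Ser5P against Ser2P). Exact permutation p-values ranged from 0.00952 to 0.0190 (5′), 0.00952 to 0.00952 (3′ and the snoRNA share) and 0.00952 to 0.0476 (antisense).

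Differences between the replicates of a group correlated across 16064 genes with r from -0.11 (GRO-seq and Ser5P) to 0.213 (total and unph). A pairing by replicate number is therefore not excluded for total and unph. With the replicate number as a block, counts were 1125 (unph), 5616 (Ser2P), 9424 (Ser5P), 14988 (GRO-seq) and 5529 (Ser5P against Ser2P) for genes, 239, 1900, 1381 and 2162 for 5′ ratios, and 2, 933, 523 and 1534 for 3′ ratios, of which only the 3′ ratio of unph moved by more than 1.5 times.

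Named genes turned in these settings. Presence counting cannot register a fold change where counts far exceed positions, as at PSBX (42628 counts on 535 positions in total, 9718 on 460 in Ser2P) and LHCB4.2 (114306 on 1209, 26245 on 1051), so turns at such genes do not bear on their calls. Gene body alone: AT4G10800 -1.10 in unph, AT4G23420 0.21 and AT3G55860 1.41 in Ser2P, STV1 0.46 in Ser5P. Small RNA genes masked: AT1G29418 -0.34 and AT3G15920 -0.00069 in unph. Presence counting: MAF5 -0.14 in unph and 0.079 in Ser5P against Ser2P; PSBX 1.502, LHCB4.2 1.59, PSAD-2 1.14, PYK10 0.43 and ERF4 0.76 in Ser2P; the 5′ ratio of LHCA2 -0.17 in Ser5P; the 3′ ratios of AT1G70420 -0.27 in unph and RBCS1A -0.014 in Ser2P. A 5′ window of 150 nt: SZF1 0.54 in unph, DOF1 0.095, MYB29 0.35, SYP111 0.26 and RPL18 1.97 in Ser2P, NF-YA2 -0.72, AT3G16800 -0.997, AT1G29660 -1.62 and LHCA2 -2.76 in Ser5P, AT1G68440 -0.69, CYCB1;4 -0.20, RPL18 2.03 and RPS5B -2.68 in GRO-seq. A 5′ window of 500 nt: AT3G07460 -0.997 and AT5G11650 -0.86 in Ser2P, AT3G16800 -0.43, AT1G29660 -0.047 and LHCA2 -0.055 in Ser5P, RBCS1B -0.15 and RPS5B -0.61 in GRO-seq. A 3′ window of 300 nt: CYP71B23 -1.24 in unph, SCD1 1.66 in Ser2P and 0.70 in Ser5P. Leaving out 1 library at a time, turning without Ser2P replicate 2, in Ser2P: the 5′ ratios of AT2G27080 (-0.51 to 4.50), LYK5 (-3.07 to 5.41), AT5G11650 (-0.21 to 4.18), HSFA7A (-3.00 to 3.81), SYP111 (-1.37 to 0.56) and CPC (-1.45 to 0.92), and the 3′ ratios of EMB2756 (-0.25 to 7.21) and SZF1 (-4.83 to 2.92).

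Ser2P replicate 1, with 612436 counts, limits what the Ser2P comparisons resolve. Ratios of exons to introns, splice site ratios, classes by exon number and organelle shares were not run, since exons and organelle positions were not used here. The 4 nuclear genes annotated as rRNA held 0 counts. Any rRNA sequence annotated under another class was not counted as rRNA.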

Other observations

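No hypothesis is tested in this part; the added gene lists were chosen after the main results had been seen.

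Further lists of heat-induced and clock-controlled genes were counted in each comparison. Of 11 tested genes of a second heat-induced list, 7 were higher and 2 lower in GRO-seq over total by edgeR (median 1.65), 5 and 2 in Ser2P over total (median 1.41), 5 and 1 in Ser5P over total (median 0.65), 1 and 0 in unph over total (median 0.10) and 1 and 6 in Ser5P over Ser2P (median -1.03). The GRO-seq set was not the same: it held APX2 (5.33) in place of AT-HSFA7B, which was tested in the NET-seq comparisons only. Of 7 clock-controlled genes of dawn or morning, 7 fell in Ser5P over total (median -2.47) and in GRO-seq over total (median -2.75), and 2 fell in Ser2P over total (median -0.35). Of 5 afternoon or evening genes, 3 rose in Ser5P over total (median 1.08), 4 fell and 1 rose in GRO-seq over total (median -3.07), and 3 fell in Ser2P over total (median -0.64). In unph over total, 0 of the 7 morning genes were called (median -0.18), and 2 of the 5 evening genes fell and 0 rose (median -0.73). In Ser5P over Ser2P, 7 morning genes fell (median -2.13), and 4 evening genes rose and 0 fell (median 2.00).

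The highest position of total Pol II lay on the minus strand of chromosome 2 at 14522476 (TAIR10), 48 nt beyond the annotated 3′ end of LHB1B2 (AT2G34420), a light-harvesting gene with near-identical copies, with a mean of 459.7 CPM. In GRO-seq the highest position lay on the minus strand of chromosome 1 at 5298177, inside the noncoding genes AT1G05163 and AT1G15405, with a mean of 849.5 CPM. The next highest GRO-seq position was at 14201659 on the plus strand of chromosome 3, inside AT3G06365, with a mean of 788.3 CPM. All further positions listed among the highest of GRO-seq lay inside the same gene, between 14201476 and 14201679. The gene is annotated as misc_RNA and was not counted as rRNA.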
